A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

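The samples were pools of designed promoters in Saccharomyces cerevisiae, strain BY4741 with the genotype sir4D, both per the labels. The labels list 10 samples in as many groups, and the 9 with tables were analysed; the LEU3 deletion was not analysed here. Per the labels' protocols, synthetic promoters were cloned by Gibson assembly into a reporter plasmid, grown in bacteria, and carried by yeast, and after sorting the plasmid DNA was recovered and amplified by PCR. The software, the sorting gates and the read processing are not given in the sources used here.

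Each deposited table holds raw read counts of each 12-base barcode in 8 sort bins, the mean fluorescence signal of each bin on the cytometer's scale, and a relative expression signal computed by the authors, all per the file headers. No header states the formula of this signal. It was recovered from the values as the sum over bins of reads × bin fluorescence × (all reads of the library / reads of the bin), divided by the raw reads of the barcode. The recomputed value was within 0.5% of the deposited signal in all rows with a value, except 904 of 1362 rows of the library with TEA1 present, where the deposited column followed another row order. Because the bins are scaled in the numerator alone, the measure weights scarce bins heavily. In the GAL4 library labelled minus galactose, reads per bin ran from 5528 to 121310, a ratio of 21.9, and the weight of the bin with fewest reads exceeded those of the 4 bins above it. The other libraries had ratios of 1.25 to 5.54. For this reason 3 measures were computed, the authors' formula as the main one, the same sum with bins scaled in both numerator and denominator, and the mean bin fluorescence over raw reads. All comparisons used log2 of the measure.

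Some columns were found by their content because headers of label columns were exchanged in 2 tables. Promoter names for the LEU3 library labelled plus leucine were taken from the other LEU3 table by sequence. In both TEA1 tables the label column was ordered differently from the sequence and read columns for 908 rows. As deposited, 24 of 1139 groups of 1 label and 1 sequence held a multiple of 3 barcodes. After pairing the blocks in order all 453 did. That count was fixed in advance, because the pairing gives all barcodes of a sequence 1 label. With TEA1 present, the deposited signals taken in label order matched the recomputed values in all 1362 rows under this pairing. The TEA1 deletion table allows no such check, since its signals matched the reads on the same row. For the library with TEA1 present, barcodes of 1 sequence had an intraclass correlation of 0.675 for values recomputed from reads on the same row and −0.063 for the deposited column, so recomputed values were used in all libraries. Of 41 gene names in the promoter labels, 38 were found in the gene table of the R64 assembly; Rg12, Mpr20 and RIO were not and are kept as labelled. No genome sequence was used, so no coordinates are given.

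Barcodes with under 10 reads were left out. They numbered 4 in the GAL4 library labelled minus galactose, 1 each in the LEU3 library labelled minus leucine and the TEA1 deletion library, 6 with YRM1 present and 7 with YRM1 deleted. Total reads were 663143, 336048 and 511408 in the GAL4 libraries (labelled plus galactose, labelled minus galactose, deleted), 600100 and 1009973 in the LEU3 libraries (labelled plus and minus leucine), 706432 and 294388 in the TEA1 libraries and 410048 and 367872 in the YRM1 libraries (present, deleted). Barcodes under 100 reads were most frequent in the TEA1 deletion library (288 of 1362) and the GAL4 library labelled minus galactose (214 of 1710). Reads are PCR products without molecular identifiers and not independent molecules, and the number of sorted cells is not known here. Barcodes of a design are technical repeats inside 1 pool, so their SD covers barcode, sorting and counting error in that library. The value of a design is the mean over its barcodes on the log2 scale. Designs had 3 barcodes, except 1 with 6 in each of the GAL4, LEU3 and TEA1 pools.

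Half-sites were counted as CGG or CCG triplets in the design sequence. Before the data were examined, the pairs of libraries, the site classes, the spacing of paired sites (CGG and CCG 11 bases apart for Gal4, CCG and CGG 4 apart for Leu3, CGG and CCG 10 apart for Tea1, the palindrome CCGCGG for Yrm1) and the tests were fixed. The spacings define the motif classes alone. Altered paired sites are those that the design labels call altered canonical sites. Differences between libraries have no test. They are medians of log2 ratios over designs with 95% percentile bootstrap intervals of 10000 resamples. Over 5 or fewer promoters such an interval equals the lowest and highest promoter, which are given instead. Effects of altered sites are altered minus unaltered promoter, tested by a two-sided exact sign-flip test over promoters with Benjamini-Hochberg adjustment over 81 tests. With 5 promoters this exact test cannot go below p = 0.0625. Medians per motif class were set against 10000 random lists of equal size, matched on expression in 10 groups but not on promoter.

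The following were chosen after the data were seen. A two-sided exact permutation test compared the 3 barcodes of an unaltered promoter with the 6 of its 2 altered versions, over 84 splits, adjusted over 90 tests. The exception was HAP4 in the GAL4 library labelled minus galactose, with 5 altered barcodes and 56 splits, where the smallest exact p is 0.0179. Elsewhere the smallest p of this exact test is 0.0119, adjusted 0.0446. All calls share this value, so enough added tests with larger p would have ended them all. In this family a call needed a complete separation of barcodes and no other split with as large an absolute difference. A miss therefore need not mean that barcodes overlapped. The 6 barcodes belong to 2 sequences, so the test speaks of these versions only. Slopes per half-site were fitted by least squares with an intercept per promoter over designs with half-sites replaced in graded numbers (GC content falls) or removed with the GC content kept, with bootstrap intervals over designs. Insertion series compared 13 designs with inserted half-sites with 7 GC controls and 7 random controls per promoter.

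The rule for named promoters, fixed beforehand, took the 10 highest and 10 lowest differences and each member present of lists of known Gal4, Leu3 and Yrm1 targets. The members present were GAL1, GAL10, GAL7, GAL2 and GCY1 for Gal4 and LEU1, LEU4, BAT1 and BAP2 for Leu3, with none for Yrm1. The pools hold 10, 9, 5 and 8 promoters, so the rule excludes none. The transcripts of the deleted factors were not measured. GAL1-GAL10 was low with GAL4 deleted (2026), but also with GAL4 present in the library labelled plus galactose (1533). The values therefore give no check of a deletion.

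The scripts were tested on simulated sorts with 50 designs changed by each known amount, at the real bin reads. The sign was right in at least 47 of 50 at each size. In the GAL4 library labelled minus galactose the authors' formula gave −1.37 for a true change of −1 and the measure scaled in both places gave −0.95. A true slope of 0.1 was recovered by the authors' formula as 0.106 to 0.154 over the 9 libraries. The measure scaled in both places gave 0.120 to 0.156 and mean bin fluorescence 0.123 to 0.159. Slopes in these simulated sorts thus run high with every measure, by amounts that differ between libraries. Alternatives covered the minimum of reads, the scale, centring, the measure, single promoters, the spacing and the TEA1 labels. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.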

Results

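Reporter expression was measured for pools of designed promoters in budding yeast, one pool for each of the zinc cluster transcription factors Gal4, Leu3, Tea1 and Yrm1. These factors bind CGG triplets, usually as pairs at a fixed spacing, and the series title names binding to single triplets (half-sites) as its subject. Each design was a promoter fragment, most often of 170 bases, placed before a yellow fluorescent protein gene. Cells were sorted into 8 fluorescence bins, and the reads of each design's barcodes, 3 in nearly all designs, were counted in each bin. There were 9 libraries, 1 per group. The GAL4 pool of 569 designs was measured with GAL4 present under labels plus and minus galactose, and with GAL4 deleted under the label minus galactose. The LEU3 pool of 450 designs was measured with LEU3 present under labels plus and minus leucine, and the LEU3 deletion was not analysed here. The TEA1 pool of 453 designs and the YRM1 pool of 528 designs were each measured with the factor present and deleted, where the title of the YRM1 deletion reads YRM11 and was taken as YRM1.

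Depth was lowest in the TEA1 deletion library, with 294388 reads and a median of 175 reads per barcode, and in the GAL4 library labelled minus galactose, with 336048 reads and a median of 174. It was highest in the LEU3 library labelled minus leucine, with 1009973 reads and a median of 721. The SD between barcodes of 1 design ran from 0.21 (log2) in the GAL4 library labelled plus galactose to 0.45 in the one labelled minus galactose. The share of the variance that lay between designs rather than between barcodes (intraclass correlation) ran from 0.526 in the TEA1 deletion library to 0.849 in the LEU3 library labelled plus leucine. Values are relative expression in arbitrary units, given as mean ± SD over 3 barcodes of an unaltered promoter and over 6 barcodes of 2 altered versions. With 1 library per group, no difference between libraries has a replicate check. All intervals cover the spread between designs, promoters or barcodes of these libraries.

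The GAL4 comparison asked how far promoters depend on paired Gal4 sites, on single half-sites and on the factor. The GAL1-GAL10 promoter, which drives the galactokinase and epimerase genes of galactose use in both directions, gave 15767 ± 1018 with GAL4 present in the library labelled minus galactose. It gave 2026 ± 210 with GAL4 deleted and 1533 ± 359 in the library labelled plus galactose. GAL1 and GAL10 are known to be induced by galactose and to need Gal4, so the labels of the 2 libraries with GAL4 go against this known direction, and they are called by their labels throughout. Altering the paired sites of GAL1-GAL10, which left 3 of its 9 half-sites, gave 686 ± 177 in the library labelled minus galactose, a log2 difference of −4.56. The same alteration gave a difference of −0.48 with GAL4 deleted and −0.47 in the library labelled plus galactose. When the bins were also scaled in the denominator, a measure chosen after the data were seen, the difference in the library labelled minus galactose was −2.96, against −0.43 with GAL4 deleted and −0.53 in the library labelled plus galactose.

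In the other promoters with an altered paired site the differences in the library labelled minus galactose were −1.09 for RIO-GCY1, upstream of an aldo-keto reductase gene, −0.68 for TIM9, a mitochondrial import gene, and −0.57 for RUP1-SFL1. With GAL4 deleted they were −0.19, 0.33 and 0.10. With the bins scaled in the denominator too, unaltered minus altered was 1.05, 0.42 and 0.54 in the library labelled minus galactose. With GAL4 deleted it was 0.23, −0.26 and −0.07. The effect was thus more negative with GAL4 present in 4 of 4 promoters, by a median of −0.95 (lowest and highest promoter −4.07 and −0.67). With 4 promoters the exact two-sided sign-flip test cannot go below p = 0.125, so no call could be made. GAL2 and GAL7, a galactose permease gene and a gene of galactose breakdown, entered the pool only with their half-sites removed and new ones inserted, and are given with the insertions.

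Replacing every half-site in GAL1-GAL10, ADR1 (an activator of genes for growth on ethanol), HAP4 (an activator of respiratory genes), STP4 and GID8 (a subunit of a ubiquitin ligase acting on gluconeogenic enzymes) gave lower values in 5 of 5 promoters in each of the 3 GAL4 libraries. The mean log2 difference was −2.22 ± 1.28 (SD, n = 5 promoters) with GAL4 present in the library labelled minus galactose, −0.70 ± 0.28 with GAL4 deleted and −0.68 ± 0.42 in the library labelled plus galactose. Tested over barcodes, GAL1-GAL10 fell from 15767 ± 1018 to 875 ± 260 in the library labelled minus galactose (exact permutation p = 0.0119, adjusted p = 0.0446). HAP4 fell from 3378 ± 724 to 1643 ± 331 with GAL4 deleted, and from 2346 ± 151 to 1095 ± 221 in the library labelled plus galactose (exact permutation p = 0.0119 and adjusted p = 0.0446 in both). ADR1 and STP4 also fell in the library labelled plus galactose. In the library labelled minus galactose, ADR1 was at 8105 ± 564 unaltered and 2325 ± 1567 altered, which missed the threshold (exact permutation p = 0.0238, adjusted p = 0.0612). Its barcodes did not overlap there, but another split gave at least as large an absolute difference. HAP4 was at 5971 ± 1614 and 1180 ± 532 there, with 5 altered barcodes, and had the smallest p that its 56 splits allow (exact permutation p = 0.0179, adjusted p = 0.0612), so it could not pass. GID8 passed in none of the 3 libraries, with differences of −0.74, −0.54 and −0.11 in the order of the means above.

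**Figure D1:**
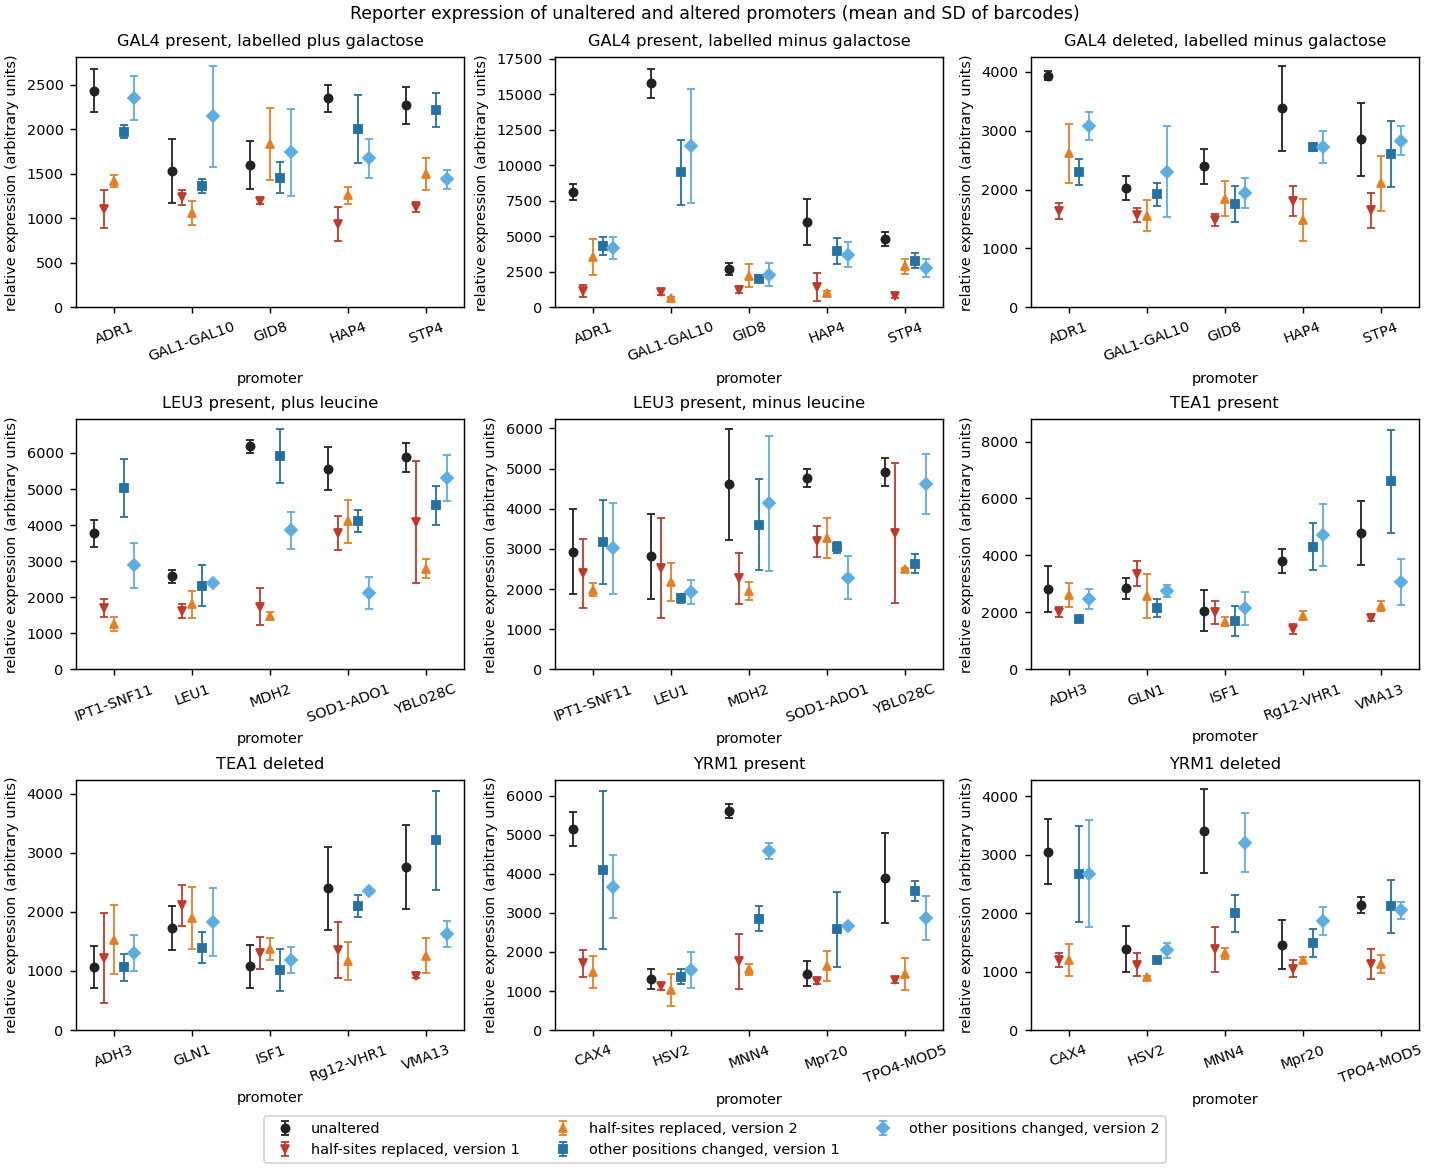
Relative expression (arbitrary units, linear axes from 0) of the 5 fully altered promoters of each pool in each of the 9 libraries, as the mean and SD of 3 barcodes for the unaltered promoter, 2 versions with half-sites replaced and 2 versions with other positions changed. Versions with half-sites replaced had the lower mean in 41 of 45 promoter and library combinations, and GAL1-GAL10 in the GAL4 library labelled minus galactose went from 15767 to 875.

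The effect of replacing half-sites was more negative with GAL4 present than deleted in 5 of 5 promoters of the libraries labelled minus galactose, by a median of −1.16 (lowest and highest promoter −3.84 and −0.20). With the bins scaled in the denominator too it was −0.71, and GID8 turned, at −0.45 with GAL4 present and −0.52 deleted. Between the 2 libraries with GAL4, the effect differed by a median of 1.13 (promoters from 0.63 to 3.82), and by 0.51 with that scaling. Other changed positions gave smaller mean differences of −0.65 ± 0.21, −0.26 ± 0.24 and −0.15 ± 0.23 in the same order of libraries. ADR1 and STP4 fell with these changes too in the library labelled minus galactose (exact permutation p = 0.0119, adjusted p = 0.0446 for both), to 4255 ± 624 and 3016 ± 601.

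Half-sites were also replaced in graded numbers in ADR1, GID8, HAP4 and STP4, which hold 13 to 19. Expression was higher with each half-site left, by 0.152 (log2; 95% bootstrap interval 0.143 to 0.161 over 267 designs) with GAL4 present in the library labelled minus galactose. The slope was 0.076 (0.072 to 0.081) with GAL4 deleted and 0.052 (0.046 to 0.057) in the library labelled plus galactose. HAP4 had the steepest slope of the 4 promoters in all 3 libraries, at 0.221, 0.108 and 0.070. The slope with GAL4 present exceeded that with GAL4 deleted by 0.076 (0.068 to 0.083), and by 0.040 with the bins scaled in the denominator. The slope in the library labelled plus galactose differed from that in the one labelled minus galactose by −0.100 (−0.108 to −0.093), and by −0.054 with that scaling. Where half-sites were removed with the GC content kept, the slopes were lower, at 0.046 (0.021 to 0.074), 0.034 (0.020 to 0.050) and 0.006 (−0.008 to 0.022), and the difference between GAL4 present and deleted was 0.012 (−0.006 to 0.032). In that series HAP4 and STP4 had slopes above 0 in all 3 libraries. ADR1 had intervals that included 0 in all 3.

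**Figure D2:**
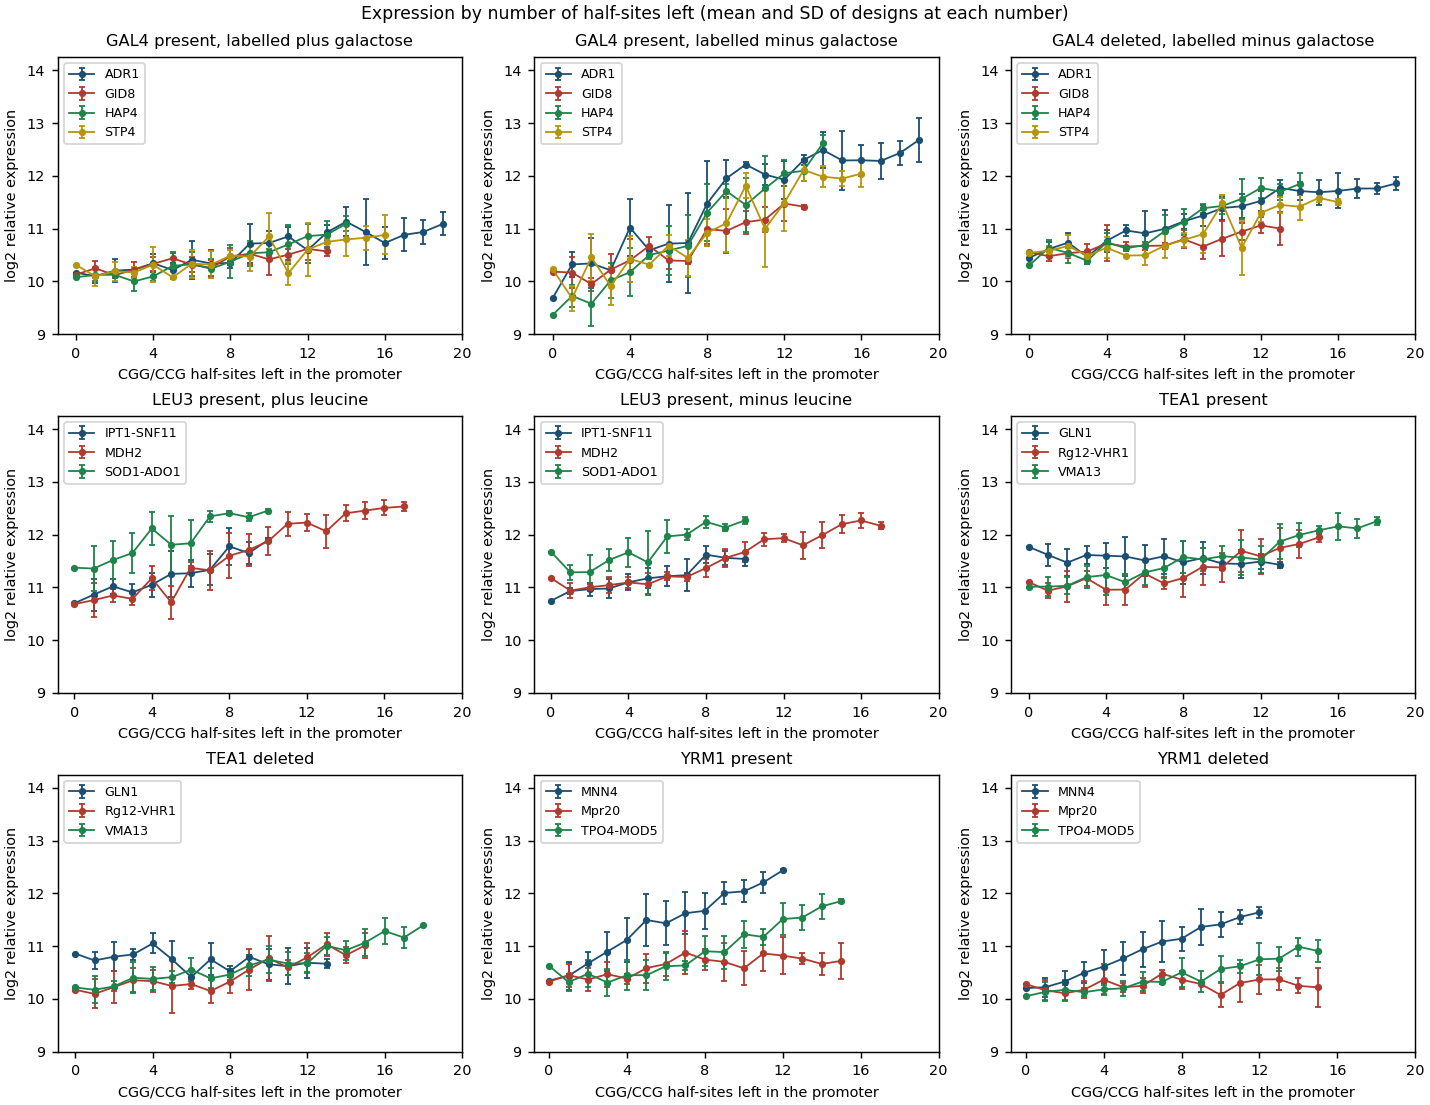
Mean log2 relative expression against the number of CGG or CCG half-sites left (0 to 19) in the promoters altered in graded steps, 1 panel per library, with bars for the SD of the designs at each number and no bar where there was 1 design. The lines of ADR1, HAP4 and STP4 are steepest in the GAL4 library labelled minus galactose, where the slope was 0.152 per half-site, and that of GLN1 is near flat in both TEA1 libraries.

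The LEU3 comparison set the library labelled plus leucine against the one labelled minus leucine, both with LEU3 present. Leu3 regulates genes of branched-chain amino acid synthesis and is known to activate them when its cofactor, a leucine precursor, is abundant. LEU4, the gene of the enzyme that makes this precursor, gave 4048 ± 1205 in the library labelled plus leucine and 2327 ± 335 in the one labelled minus leucine. With its paired site altered it gave 1450 ± 192 and 2409 ± 242, so that the log2 effect was −1.45 in the first and 0.05 in the second. Leucine is known to inhibit the enzyme that LEU4 encodes, so the higher LEU4 value and larger site effect under the label plus leucine go against the known direction, and these libraries too are called by their labels. For LEU1, which encodes the next enzyme of leucine synthesis, the effects were −0.68 and −0.36. For BAP2, a branched-chain amino acid permease gene, they were −0.69 and −0.51, and for VPH1, a gene of the vacuolar proton pump, −0.43 and 0.23. YBL028C went the other way, with −0.31 and −0.79. Over 5 promoters the paired site effect was negative in 5 in the library labelled plus leucine (exact sign-flip p = 0.0625, adjusted p = 0.241). It was negative in 3 in the other library (exact sign-flip p = 0.25, adjusted p = 0.368). The median difference between the libraries was −0.32, with promoters from −1.51 to 0.49.

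Replacing every half-site gave lower values in 5 of 5 promoters in both libraries, of which 3 passed the test in the library labelled plus leucine. MDH2, the cytosolic malate dehydrogenase gene, fell from 6178 ± 168 to 1608 ± 369, IPT1-SNF11 from 3768 ± 368 to 1477 ± 309 and LEU1 from 2585 ± 183 to 1707 ± 284 (exact permutation p = 0.0119 and adjusted p = 0.0446 for each). In the library labelled minus leucine 2 passed (exact permutation p = 0.0119 and adjusted p = 0.0446 for each). These were MDH2, which fell from 4612 ± 1381 to 2111 ± 458, and SOD1-ADO1, between the superoxide dismutase and adenosine kinase genes, from 4762 ± 221 to 3231 ± 404. SOD1-ADO1 and LEU1 also fell there with other positions changed (exact permutation p = 0.0119, adjusted p = 0.0446 for both), to 2664 ± 538 and 1844 ± 216. YBL028C, a gene named by its locus, had differences of −0.84 and −0.81 and passed in neither library. The mean effect of half-site replacement over 5 promoters was −1.06 ± 0.61 and −0.63 ± 0.34. Its median difference between the libraries was −0.35 (promoters from −0.99 to 0.07), or −0.19 without the promoter of the largest effect.

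In the graded series of IPT1-SNF11, MDH2 and SOD1-ADO1 the slope per half-site was 0.121 (0.113 to 0.129 over 174 designs) in the library labelled plus leucine and 0.091 (0.085 to 0.097) in the one labelled minus leucine. The difference was 0.030 (0.023 to 0.038). With the GC content kept, the slopes were 0.098 (0.069 to 0.119) and 0.065 (0.045 to 0.085), and all 3 promoters had intervals above 0 in both libraries. The difference in that series was 0.033 (0.009 to 0.052).

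The TEA1 comparison set the factor present against deleted. Tea1 is known as an activator of Ty1 element enhancers. Altering the paired site gave log2 differences of −0.25 for ADH3, the mitochondrial alcohol dehydrogenase gene, and −0.49 for ISF1 with TEA1 present, and of 0.06 and −0.01 with TEA1 deleted. With the bins scaled in the denominator too, unaltered minus altered was 0.38 for ADH3 and 0.21 for ISF1 with TEA1 present. With TEA1 deleted it was −0.04 and −0.09. Values for ISF1 were 2065 ± 707 unaltered and 1416 ± 168 altered with TEA1 present, so the difference was within the SD of the unaltered promoter. With 2 promoters the exact sign-flip test allows no p below 0.5. Replacing every half-site lowered VMA13, a gene of the vacuolar proton pump, from 4782 ± 1123 to 2011 ± 259 with TEA1 present and from 2752 ± 711 to 1085 ± 265 with TEA1 deleted (exact permutation p = 0.0119, adjusted p = 0.0446 for both). Rg12-VHR1 fell from 3813 ± 422 to 1655 ± 298 with TEA1 present (exact permutation p = 0.0119, adjusted p = 0.0446). With TEA1 deleted it was at 2398 ± 702 and 1260 ± 378, which missed the threshold (exact permutation p = 0.0238, adjusted p = 0.0612). GLN1, the glutamine synthetase gene, was at 2850 ± 369 and 2969 ± 712 with TEA1 present and passed in neither library. With TEA1 deleted, 3 of 5 promoters had higher means after replacement, ADH3 by 0.29, GLN1 by 0.21 and ISF1 by 0.35 (log2), and none of these passed. The median difference of the half-site effect between the libraries was −0.28 (promoters from −0.55 to 0.11).

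The graded slope was 0.060 (0.055 to 0.066 over 237 designs) with TEA1 present and 0.052 (0.046 to 0.058) with TEA1 deleted, a difference of 0.008 (0.001 to 0.015). That difference reversed to −0.008 with the bins scaled in the denominator. VMA13 and Rg12-VHR1 had slopes above 0 in both libraries, and GLN1 had slopes of −0.012 (−0.025 to 0.001) and −0.015. With the GC content kept the slopes were 0.021 (0.007 to 0.033) and 0.013 (−0.002 to 0.029), of which Rg12-VHR1 had 0.060 and 0.049 and VMA13 had intervals that included 0. In the tables of both TEA1 libraries, 908 of 1362 barcodes stood beside the label entry of another design, which may read the same. The values above follow labels paired again with their sequences. With the labels as they stand, the mean effect of replacing half-sites was 0.03 with TEA1 present in place of −0.56, and 0.0005 with TEA1 deleted in place of −0.29. With labels paired again, the mean of −0.29 with TEA1 deleted was −0.02 without VMA13.

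The YRM1 comparison likewise set the factor present against deleted. Yrm1 is known as an activator of drug resistance genes, none of which from the list fixed beforehand was among the promoters. Replacing every half-site gave lower values in 5 of 5 promoters in both libraries, and the same 3 passed the test in both (exact permutation p = 0.0119 and adjusted p = 0.0446 for each). CAX4, a gene of dolichol recycling for protein glycosylation, fell from 5149 ± 431 to 1600 ± 363 with YRM1 present and from 3050 ± 556 to 1202 ± 188 with YRM1 deleted. MNN4, a regulator of mannan phosphorylation, fell from 5602 ± 181 to 1656 ± 462 and from 3403 ± 712 to 1346 ± 256. TPO4-MOD5, between a polyamine transporter gene and a tRNA modification gene, fell from 3896 ± 1157 to 1356 ± 278 and from 2133 ± 135 to 1130 ± 190. HSV2 and Mpr20 passed in neither library. Other changed positions raised Mpr20 from 1447 ± 327 to 2616 ± 608 with YRM1 present (exact permutation p = 0.0119, adjusted p = 0.0446), and gave 1678 ± 300 against 1462 ± 419 with YRM1 deleted, which did not pass.

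The mean effect of half-site replacement was −1.07 ± 0.85 with YRM1 present and −0.88 ± 0.48 with YRM1 deleted (n = 5 promoters each). Its median difference was −0.38 (promoters from −0.57 to 0.34), and was −0.12 without the promoter of the largest effect. Altering the sites labelled canonical gave mean differences of −0.24 ± 0.24 and −0.18 ± 0.17 over 5 promoters (exact sign-flip p = 0.125, adjusted p = 0.241 in both). Whether these sites are the palindrome CCGCGG was not checked. The graded slope was 0.087 (0.078 to 0.095 over 237 designs) with YRM1 present and 0.054 (0.047 to 0.060) with YRM1 deleted, a difference of 0.033 (0.027 to 0.039). MNN4 had the steepest slopes, 0.173 and 0.133, then TPO4-MOD5 with 0.110 and 0.063, while Mpr20 had 0.024 and 0.008. With the GC content kept the slopes were 0.035 and 0.027, and their difference was 0.008 (−0.008 to 0.026).

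**Figure D3:**
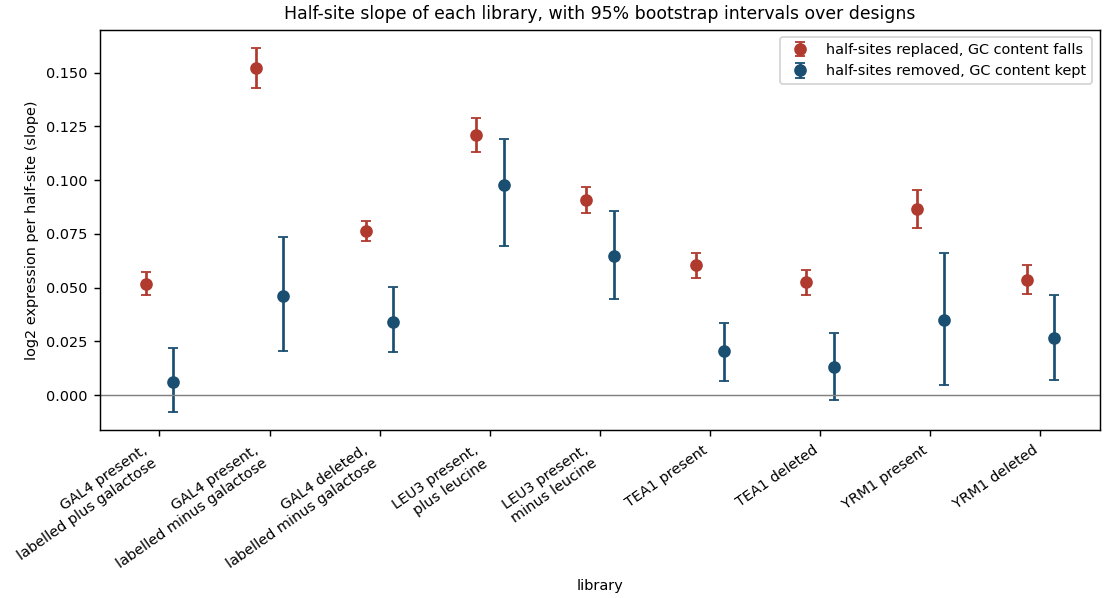
Change in log2 relative expression per half-site left in each of the 9 libraries, with 95% bootstrap intervals over designs, for designs that lost GC content with their half-sites and designs that kept it. All 9 slopes in the first series lie above 0, from 0.052 to 0.152, and each slope with GC content kept lies below its partner.

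Inserting half-sites into promoters stripped of them asked whether half-sites are enough to raise expression. In all 32 combinations of promoter and library, the 13 designs with inserted half-sites had a higher mean than the 7 with random triplets, and each interval lay above 0. They also had a higher mean than the 7 with GC control insertions in all 32, where 19 intervals lay above 0. The means were not adjusted for GC content, so a difference in GC content between the 13 and the 7 is not excluded. RUP1-SFL1 had the widest span from fewest to most half-sites, from 1010 ± 581 with 1 half-site to 10963 ± 1613 with 32, with GAL4 present in the library labelled minus galactose. GC content rises along such a span, and the designs of this promoter exceeded its GC controls there by 0.28 (log2; −0.65 to 1.30), which includes 0. It went from 1661 ± 359 to 4681 ± 510 with GAL4 deleted. GAL7 went from 910 ± 423 with 1 half-site to 4983 ± 918 with 31 in the library labelled minus galactose, and from 1390 ± 131 to 3410 ± 338 with GAL4 deleted. Its excess over GC controls also included 0 in both, at 0.67 (−0.27 to 1.63) and 0.41 (−0.01 to 0.83). GAL2 went from 1535 ± 474 with 2 half-sites to 5811 ± 1994 with 31 in the library labelled minus galactose, where the excess was 0.59 (0.06 to 1.10), and from 1846 ± 179 to 4182 ± 64.2 with GAL4 deleted, where it was 0.29 (−0.19 to 0.70). For GAL1-GAL10 the excess was 0.94 (0.30 to 1.55) in the library labelled minus galactose and 0.33 (−0.01 to 0.65) with GAL4 deleted. LEU1 went from 1739 ± 85.3 with 2 to 6746 ± 394 with 30 in the library labelled plus leucine, and from 2082 ± 293 to 4079 ± 522 in the one labelled minus leucine. BAT1, a branched-chain aminotransferase gene, went from 1528 ± 166 with 2 to 5758 ± 314 with 31 and from 1893 ± 257 to 3611 ± 531. Both promoters exceeded their GC controls in both libraries with intervals above 0, as did ISF1 and CAX4 below and ADH3, HSV2 and GIP3-ISU1. The excess of LEU4 included 0 in both, at 0.55 (−0.03 to 1.10) labelled plus leucine and 0.13 (−0.13 to 0.38) labelled minus leucine. For YBL028C it was 0.46 (0.19 to 0.72) and 0.10 (−0.10 to 0.29). SPO24 included 0 with YRM1 present, at 0.39 (−0.15 to 1.02), and deleted, at 0.24 (−0.10 to 0.57). ISF1 went from 1605 ± 250 to 5737 ± 1695 with TEA1 present and from 1200 ± 610 to 2928 ± 282 with TEA1 deleted. CAX4 went from 1244 ± 68.5 to 6137 ± 537 with YRM1 present and from 968 ± 48.6 to 3896 ± 179 with YRM1 deleted.

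Against the GC controls, inserted half-sites gave mean log2 differences of 0.62 ± 0.27 (SD, n = 4 promoters) with GAL4 present in the library labelled minus galactose, 0.27 ± 0.16 with GAL4 deleted and 0.44 ± 0.18 in the library labelled plus galactose. No single interval lay above 0 with GAL4 deleted. For LEU3 the differences were 0.58 ± 0.10 in the library labelled plus leucine and 0.24 ± 0.15 in the one labelled minus leucine. For YRM1 they were 0.70 ± 0.21 with the factor and 0.50 ± 0.25 without. The 2 TEA1 promoters gave 0.75 ± 0.15 with the factor and 0.61 ± 0.05 without. With the bins scaled in the denominator too this order turned, at 0.83 without the factor and at most 0.77 with it. The difference between libraries had a median of 0.28 for GAL4 present against deleted (4 promoters from 0.23 to 0.62), 0.35 for LEU3 (4 from 0.27 to 0.42), 0.20 for YRM1 (4 from 0.04 to 0.38) and 0.13 for TEA1 (2, −0.01 and 0.27). For GAL4 in the library labelled plus against that labelled minus galactose it was −0.23 (4 from −0.30 to 0.02). So few promoters allow no call.

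**Figure D4:**
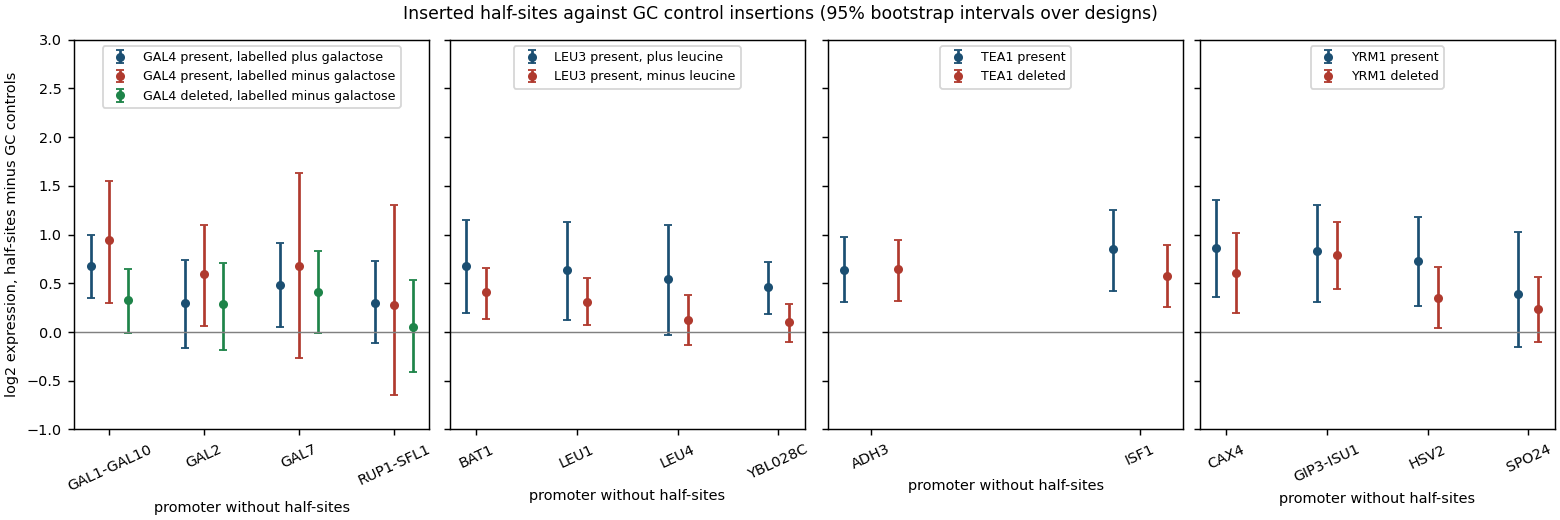
Mean log2 expression of promoters with inserted half-sites minus that of promoters with GC control insertions, for each promoter background and library, with 95% bootstrap intervals over designs. All 32 points lie above 0, and 19 intervals do.

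Half-sites were also rearranged. Turning all of them to 1 orientation gave mean differences between −0.73 ± 1.01 (GAL4 present, labelled minus galactose) and 0.07 ± 0.35 (TEA1 deleted). Moving them gave lower means in all 9 libraries, from −1.08 ± 0.96 in the GAL4 library labelled minus galactose to −0.09 ± 0.21 in the one labelled plus galactose, though moved designs held fewer half-sites in ADR1, for example 10 to 15 in place of 19. GAL1-GAL10 carried much of both means in the library labelled minus galactose, at −2.46 and −2.76 where the medians over promoters were −0.44 and −0.74. The exact two-sided sign-flip test over promoters covered 81 combinations of library and class of change. With 5 promoters it cannot go below p = 0.0625, so none could pass 0.05, and after adjustment the lowest value of this exact test was p = 0.241. The exact permutation test over barcodes, chosen after the data were seen, covered 90 combinations. It called half-site replacement lower in 19 of 45 and higher in 0, and other changed positions lower in 4 of 45 and higher in 1.

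Over whole pools, expression with GAL4 present and deleted differed by a median log2 ratio of 0.24 (0.21 to 0.31 over 569 designs), which turned to −0.05 for mean bin fluorescence over raw reads. Relative to this shift, unaltered GAL1-GAL10 was higher with GAL4 present by 2.72, RUP1-SFL1 by 0.92, ADR1 by 0.80 and RIO-GCY1 by 0.76, while TIM9 stood at −0.95. The library labelled plus galactose was lower than the one labelled minus galactose by a median of −0.75 (−0.81 to −0.68), or −0.28 for mean bin fluorescence. The library labelled plus leucine was higher than the one labelled minus leucine by 0.14 (0.11 to 0.18), or 0.23 for mean bin fluorescence. Relative to that shift LEU4 stood at 0.63, BAP2 at 0.24 and LEU1 at −0.20. TEA1 present exceeded deleted by 0.82 (0.79 to 0.86), in 452 of 453 designs, or by 0.54 for mean bin fluorescence. YRM1 present exceeded deleted by 0.51 (0.48 to 0.54), in 501 of 528. Bin fluorescence differed between libraries, so these shifts are not on a common scale.

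Designs with a paired site at the known spacing stood apart from random lists in 2 of the 5 pairs. The lists were matched on expression and not on promoter, while ratios differed between promoters. With GAL4 present against deleted, for example, the median ratio was 0.54 over ADR1 designs and −0.25 over GAL7 designs. The percentiles therefore do not separate the paired site from the promoters that hold it. With GAL4 present against deleted, 44 designs with CGG and CCG 11 bases apart had a median ratio of 0.77 (0.66 to 0.90), at the 100th percentile of random lists matched on expression, whose median was 0.62. The 453 designs with half-sites alone had 0.25, and the 72 with neither had −0.46, at percentile 0.12. In the library labelled plus against that labelled minus galactose, designs with the paired site had −1.20 at percentile 58.3, where random lists had −1.21. For leucine, 48 designs with CCG and CGG 4 bases apart had 0.44 (0.34 to 0.65), again at the 100th percentile, against 0.16 with half-sites alone. For TEA1 the 103 designs with CGG and CCG 10 bases apart had 0.93 at percentile 96.1 against 0.80 with half-sites alone, a difference that reversed to −0.03 with the bins scaled in the denominator. For YRM1 the 74 with the palindrome had 0.50 and those with half-sites alone 0.54. Across designs, which are not replicates, Pearson's r between libraries of a pool ran from 0.82 for TEA1 to 0.93 for YRM1, with Spearman's rho of 0.83 and 0.90.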

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

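The tests of the galactose labels and the bin weighting were chosen after the result was seen, and the slopes themselves were defined after the data were seen; the other tests here were set before their results.

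By the authors' formula the half-site slope differed between the libraries of each of the 5 pairs, with bootstrap intervals that exclude 0 but cover designs and not cultures, since each group has 1 library. The difference was −0.100 for GAL4 in the library labelled plus against that labelled minus galactose and 0.076 for GAL4 present against deleted (−0.054 and 0.040 with bins scaled in numerator and denominator), 0.030 for LEU3 in the library labelled plus against that labelled minus leucine, 0.033 for YRM1 present against deleted and 0.008 for TEA1 present against deleted (−0.0079 with that scaling and −0.0047 for mean bin fluorescence). A steeper slope may come from a library whose values are spread more widely for all designs, so the ratio of slopes was set against the ratio of spreads over control designs for the 3 pairs with a deletion, and not for the galactose and LEU3 pairs. These controls pool designs that keep their half-sites with control insertions into stripped promoters. For GAL4 present against deleted, designs changed outside half-sites had a median log2 ratio of 0.49 and random triplet insertions −0.87. An action through half-sites would thus widen the control spread too, so this test cannot separate the 2 explanations. For TEA1 the ratio of slopes was 1.15 (1.02 to 1.30) and the ratio of spreads 1.17. In simulated sorts, which assume a spread of cells and of barcodes, the formula turned 1 true slope of 0.1 into 0.148 with TEA1 present. With TEA1 deleted it gave 0.106, so a difference as small as that for TEA1 can arise without a difference in true slope. Slopes ran high with the other measures too, at 0.142 and 0.136 (present, deleted) with bins scaled in numerator and denominator. For mean bin fluorescence they were 0.139 and 0.126. For GAL4 the ratios were 1.99 (1.88 to 2.11) and 2.22 (2.01 to 2.44), and for YRM1 1.61 (1.48 to 1.77) and 1.48 (1.39 to 1.60). In both the intervals overlap, and the spread cannot be told apart from an action of the factor through half-sites. By the authors' formula the simulated slopes were 0.143 and 0.122 for GAL4 and 0.154 and 0.148 for YRM1 (present, deleted). These gaps were smaller than the observed differences of 0.076 and 0.033.

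Replacing half-sites went with lower expression also where the factor was deleted, with slopes of 0.076 for GAL4, 0.052 for TEA1 and 0.054 for YRM1, although 3 of 5 promoters with TEA1 deleted had higher means once every half-site was replaced. That any change of bases lowers expression is argued against by the slope per changed base outside half-sites, which was 0.117 (−0.016 to 0.245) of that inside them over the 3 deletion libraries. Lower GC content may account for a large part, since with GC content kept the slope was 0.405 (0.251 to 0.556) of that with GC content lost. It is not shown to account for the whole, because that slope stayed above 0 with GAL4 deleted (0.020 to 0.050) and with YRM1 deleted (0.007 to 0.047), though not with TEA1 deleted. Inserted half-sites exceeded GC controls with intervals above 0 in 2 of 2 promoters with TEA1 deleted and 3 of 4 with YRM1 deleted. With GAL4 deleted this held in 0 of 4. How the effect divides between GC content and other factors that bind CGG triplets stays open, and the latter was not tested.

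GAL1-GAL10 was lower in the library labelled plus galactose than in the one labelled minus galactose, against the known induction of these genes. The effect of its paired sites was larger in the library labelled minus galactose by 4.09 (log2; 3.47 to 4.71 from 2 SE over barcodes on each side), of which 3.39 comes from the unaltered promoter itself. That test therefore restates the observation, and exchanged labels cannot be told apart from another difference in growth. The weighting of scarce bins is argued against as the whole cause, since with bins scaled in numerator and denominator the difference was 2.43 (1.87 to 2.99). The deposited tables of both libraries labelled minus galactose bear names that call them induced, against their label, but a name is not a measurement, and whether the GAL4 deletion library was grown with galactose stays open as well.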

How the results depend on the processing

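The measures scaled in numerator and denominator, the mean bin fluorescence for effects inside libraries and the TEA1 labels as they stand were chosen after the data were seen. Over 53 results and 305 alternatives, 295 kept the sign and 263 were counted as unmoved. For 81 of these, mean effects of replaced half-sites inside a library, this means only that the sign was kept. Their sign-flip test over promoters was unable to cross the threshold in any setting, and no spread was checked. The others stayed within the spread of the main value. By the same rules, no setting of the minimum of reads (none, or 100) moved a result. Centring cannot move effects inside a library, their differences between libraries or differences between motif classes. Adding 1 to the values before log2, the alternative scale, changes little by construction. Library medians by the authors' formula were 1439 or more. The 263 therefore include alternatives with little or no room to move a result, and this count is not evidence of stability. Except where the construction is named, the cause was not tested. Depth limits the GAL4 library labelled minus galactose and the TEA1 deletion library most. Altered and unaltered promoters, and the same design in 2 libraries, were paired. Replicate cultures were not, because each group has 1 library.

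Centring each library on its median removes the shift between libraries by construction, and left 0.089 and −0.087 for GAL4 (labelled plus against minus galactose; present against deleted), −0.016 for LEU3, 0.041 for TEA1 and 0.055 for YRM1, so the first 3 reversed. The mean gave 0.17 for GAL4 present against deleted. Without the designs of lowest expression (25%), r was 0.726, 0.731 and 0.802 for the 3 GAL4 pairs, 0.816 for LEU3 and 0.730 for TEA1.

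With mean bin fluorescence over raw reads, the library medians were −0.28 and −0.048 (reversed) for the 2 GAL4 pairs, 0.23 for LEU3 and 0.54 for TEA1. The difference in half-site effect between the GAL4 libraries labelled plus and minus galactose was 0.62. Slopes were 0.058 and 0.132 in these 2 libraries, 0.139 labelled plus leucine and 0.062 with TEA1 deleted. Slope differences were −0.074 and 0.056 for GAL4, 0.042 for LEU3 and −0.0047 (reversed) for TEA1. Insertions exceeded GC controls by 0.70 labelled plus leucine and 0.73 with TEA1 deleted.

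With bins scaled in numerator and denominator, the GAL4 library medians were −0.58 and 0.12, and the difference in half-site effect between labelled plus and minus galactose was 0.51. Slopes were 0.111 with GAL4 labelled minus galactose, 0.071 with GAL4 deleted, 0.098 labelled minus leucine and 0.068 with TEA1 deleted. Slope differences were −0.054 and 0.040 for GAL4 and −0.0079 (reversed) for TEA1. Insertions exceeded GC controls by 0.83 with TEA1 deleted, and the TEA1 difference between paired sites and half-sites alone reversed to −0.033.

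With TEA1 labels as they stand, the effect of replacing half-sites was 0.027 with TEA1 present and 0.0005 with TEA1 deleted (both reversed), and the slopes were 0.051 and 0.043. By the pairing of blocks, the rows concerned then carry label entries of other sequences, which may read the same. One further effect inside its interval changed sign there, the TEA1 difference in half-site effect, to 0.029. Leaving out the promoter of the largest effect moved the TEA1 deletion mean from −0.29 to −0.02.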

Other observations

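The position test was set before its result. The description of single promoters was chosen after the values were seen.

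Promoters of the TEA1 and YRM1 pools differed in how far they followed their half-sites, with and without the factor. Rg12-VHR1 and VMA13 had slopes of 0.068 and 0.072 (log2) per half-site with TEA1 present, whereas GLN1, with 13 half-sites, had −0.012 (−0.025 to 0.001). Mpr20, with 15 half-sites and a GC content of 64.1%, had 0.024 with YRM1 present, and MNN4, with 12 half-sites and 45.3% GC, had 0.173. With the GC content kept, the order with YRM1 deleted was MNN4 at 0.111, TPO4-MOD5 at 0.024 and Mpr20 at −0.018. Of 30 combinations of promoter and library, 28 slopes were positive and 27 intervals lay above 0 where GC content fell. Where it was kept, 24 were positive, 18 intervals lay above 0 and 1 lay below 0, GID8 in the GAL4 library labelled plus galactose at −0.027.

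Half-sites toward the reporter may weigh more than those at the far end of the fragment, since the slope per half-site lost from the 3′ part exceeded that from the 5′ part in 7 of 9 libraries. The difference was 0.067 (0.040 to 0.091) with GAL4 deleted, 0.140 (0.096 to 0.188) with YRM1 present and 0.115 (0.082 to 0.151) with YRM1 deleted. Of these 7 it was smallest for LEU3, at 0.047 (0.004 to 0.086) in the library labelled plus leucine and 0.029 (−0.002 to 0.060), which includes 0, in the one labelled minus leucine. Both TEA1 libraries went the other way, at −0.077 (−0.115 to −0.045) and −0.055 (−0.087 to −0.023). Libraries of 1 pool share their sequences, so these are 4 sets of promoters and not 9 independent cases, and the question stays open.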
